A study of Mus musculus with 12 samples.

How the data were processed

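RNA from the striatum of C57BL/6J mice was extracted with Trizol, and polyA+ libraries were sequenced as paired reads, per the labels' protocols. The 12 libraries formed 4 groups of 3, taken from the titles. Reads were processed with HISAT2 and featureCounts on mm10, per the submitters' processing notes. Tool versions, annotation release and strand setting are not given in the sources used here. The deposited values are whole-number read counts per Ensembl gene, 1 table per library, and the authors applied no normalization to them as far as the values show. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart. All tables listed the same 54532 genes in the same order, of which 54409 had a symbol in the reference gene names, and 0 entries named no gene. Gene positions are GRCm38 coordinates from GENCODE M21 (mm10), counted from 1.

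Totals ranged from 15806076 to 18622053 counts per library. Pairs of libraries within a group differed by more than sampling noise (chi-square over degrees of freedom from 4.79 to 78.2, over genes with at least 20 counts), so no library was counted as a repeat of another. Mitochondrially encoded genes took 3.77% to 6.82% of counts.

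Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group with a minimum count of 10, which left 18537. Libraries were scaled by TMM, and all 12 were fitted in one quasi-likelihood model with group as the only term, so that the groups share one estimate of the spread. Each of the 6 pairs of groups was tested with glmQLFTest, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error of a log2 fold change is its size divided by the root of the F statistic. CPM values are TMM-scaled. Of the 28 gene lists, fixed before the data were examined, each was tested against all other genes with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. Members called were counted over all genes and adjusted over the list alone.

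Genes named in the text follow a rule fixed before the data were examined. In each comparison these were the 5 largest rises and 5 largest falls among called genes with a mean of at least 1 CPM, no overlap between the groups and a symbol that is neither a Gm or Rik name nor a pseudogene label. To these were added, for the 8 lists with the smallest camera p, the 2 called members with the smallest adjusted p, and in every comparison STING, Cgas, Tbk1, Irf3 and Ifnb1. List members could be followed through other comparisons. Other genes are said to have been chosen after their values were seen. Where every library of a group had 0 counts, the fold is a bound against 3 counts over the group. Setting list members with 0 counts in a group to such a bound left every list median given in the text as it was. With 1 to 3 counts, a ratio with an exact 95% binomial counting interval is given.

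Movement under SN-011 was measured as the covariance of differences of mean log2 CPM, beside 100 simulations of unchanged groups drawn with the dispersions of the sham and vehicle libraries. The 3 vehicle libraries could not be split into sets of 2 or more, so part of any excess can come from sharing them.

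The test was tested on simulated data with 50 genes changed by each of 4 known folds. For vehicle against sham, over 18223 genes, 14% of genes changed 1.5-fold were recovered, 56% at 2-fold, 90% at 4-fold and 96% at 8-fold, with 7 false calls among 135. For SN-011 against vehicle, over 18214 genes, the shares were 18%, 62%, 96% and 100%. The changed genes had a mean of at least 50 counts and 1 dispersion for all groups, so these shares do not carry over to the SN-011 libraries, which spread more: 0 of 23 activated microglia genes were called there at a median of 2.09 on the log2 scale. The shares also hold only where many genes change together, since the Benjamini-Hochberg cutoff loosens as more genes are called. They overstate the power for a few changed genes, as in vehicle against sham, where 0 genes were called. The smallest adjusted p there was 0.0848, for Nr4a3 (edgeR quasi-likelihood test).

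The alternatives tried were RLE scaling, DESeq2 1.42.0, no filter, a fit of the 6 libraries compared only, the replicate number as a block, a threshold on the fold change and leaving out each replicate. Added after the data were seen were a fit of the 9 libraries without the 3d arm, limma voom with quality weights, offsets for GC content and transcript length (known for 99.9% of genes) and camera with the correlation estimated in 6 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.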

Results

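Gene expression in the mouse striatum was measured by polyA+ RNA sequencing after transient middle cerebral artery occlusion, a model of ischaemic stroke in which the artery that supplies the striatum is blocked for a time and then reopened. The series asked how SN-011, an antagonist of the innate immune adaptor STING, alters the response. The 12 libraries of C57BL/6J striatum fell into 4 groups of 3: sham operation with saline, occlusion with saline vehicle, and 2 arms of occlusion with SN-011, of which 1 carries the prefix 3d in its titles. The labels give both arms the same treatment and do not say what 3d stands for, so a difference in time, dosing or tissue between the arms cannot be told from these labels. Each library held between 15806076 and 18622053 counted reads. Of 54532 genes, 18537 had enough counts to be tested. Gene positions are on GRCm38 (mm10), and every gene given a position is protein-coding in the annotation. Expression values are TMM-scaled CPM, as mean ± SD with n = 3 per group, and fold changes are on the log2 scale from edgeR. The labels do not state that the libraries of a group came from separate animals, so p-values measure a spread between samples. That spread was estimated over all 12 libraries, although the groups differed in it. Chi-square over degrees of freedom between replicates was 4.79 to 8.85 in sham, 6.86 to 19.04 in vehicle, 13.9 to 57.3 in SN-011 and 47.2 to 78.2 in the 3d arm. The p-values of vehicle against sham therefore also carry the spread of the SN-011 arms.

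The first principal component of log2 CPM held 70.6% of the variance and set the 3d arm apart from the other groups. Along it vehicle replicates 1 and 2 lay beside the sham libraries and vehicle replicate 3 lay nearer to the SN-011 arm. The SN-011 libraries were spread between these and the 3d arm, and replicate 3 lay closest to the 3d arm. Gfap, the intermediate filament of reactive astrocytes, was chosen for display after its values were seen: it stood at 107 ± 23.8 CPM in sham, at 138, 127 and 493 in the vehicle replicates 1 to 3, at 1213, 413 and 3644 in the SN-011 replicates and at 6684 ± 1531 in the 3d arm. It was not called for vehicle against sham or SN-011 against vehicle (edgeR quasi-likelihood test, adjusted p = 1 and 0.163), where replicate 3 of each group carried most of the mean.

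**Figure D1:**
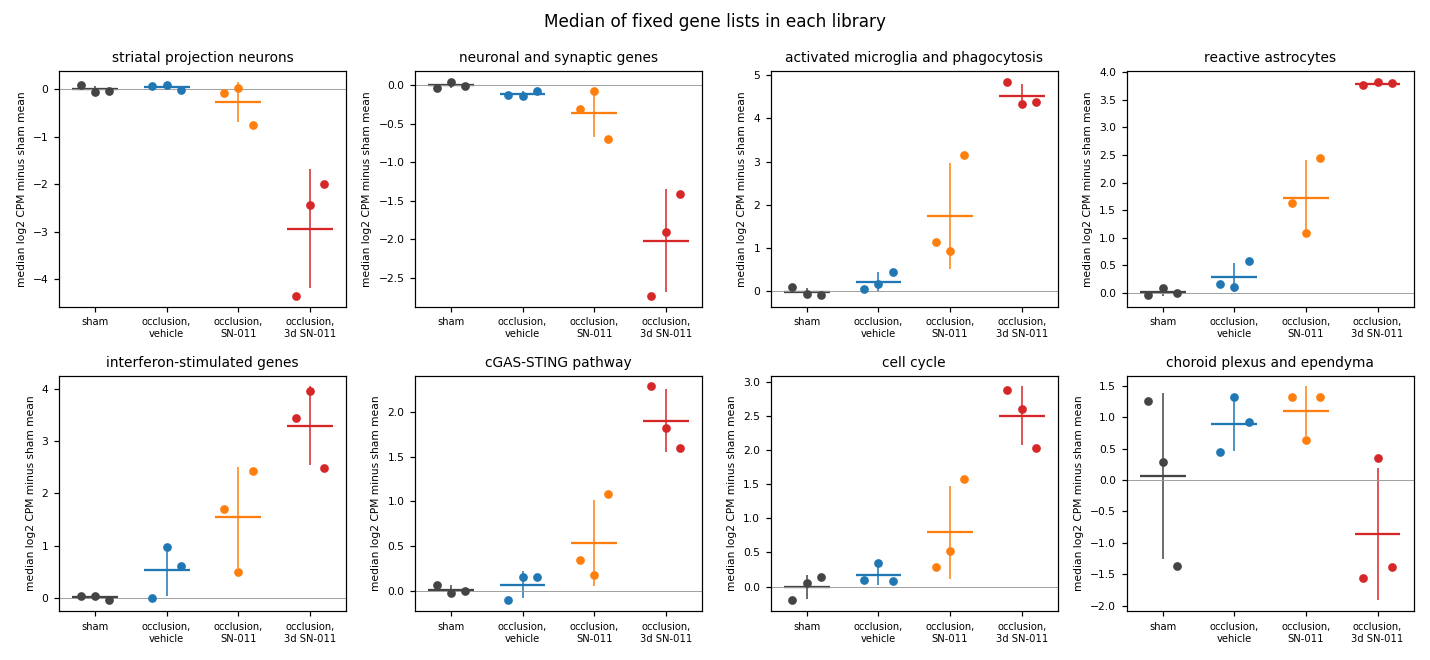
Each panel plots, for 1 fixed gene list, the median over its genes of log2 CPM minus the sham mean (y axis) in each of the 12 libraries, by group (x axis). Points are libraries, horizontal bars group means and vertical bars ± 1 SD. Activated microglia genes lay between 4.34 and 4.85 in the 3d arm and at or below 0.45 in vehicle.

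The comparison of vehicle with sham asks what the occlusion did without the drug. Few differences could be resolved. Striatal projection neuron genes had a median log2 fold change of 0.019 over 28 members, and Drd1 and Drd2, the dopamine receptors of these neurons (2 genes chosen after their values were seen), stood at 338 ± 39.7 and 388 ± 22.02 CPM against 306 ± 11.2 and 363 ± 24.5 in sham. Interferon-stimulated genes had a median of 0.52 and reactive astrocyte genes 0.28, with no member called in either list (0.23 and 0.090 without vehicle replicates 2 and 3, and 0.44 for reactive astrocytes without replicate 1). Nr4a3, an immediate early transcription factor (chromosome 4, 48045153 to 48086447), stood at 58.4 ± 4.58 CPM in vehicle and 19.04 ± 0.387 in sham, which missed the threshold (edgeR quasi-likelihood test, adjusted p = 0.0848). This was the smallest adjusted p of the comparison.

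By edgeR's quasi-likelihood test, with the spread estimated over all 12 libraries, 0 genes were called between vehicle and sham. An unadjusted p under 0.05 was reached by 467 genes in the same test, fewer than 0.05 of the 18537 tested, the share that chance alone gives. DESeq2 called 3, edgeR on these 6 libraries alone 16, and limma voom with quality weights, added after the data were seen, 32. No gene was called in the edgeR fit with any 1 sham or vehicle replicate left out. The groups did not overlap for 13.2% of genes, where chance gives 10%. Camera with its preset correlation called 9 of the 28 lists, 6 higher and 3 lower. The higher lists were interferon-stimulated genes, choroid plexus and ependyma, immediate early genes, reactive astrocytes, red blood cells and the cell cycle. The lower ones were endothelium and blood-brain barrier, lymphocytes and cortical projection neurons. None held with an estimated correlation (camera, adjusted p = 0.915 for each of the 9). Adjusted over the list alone, 3 immediate early genes were higher and 1 lower, and 1 lymphocyte gene was lower. Choroid plexus and ependyma genes, which come from tissue beside the striatum, also varied within groups: the sham libraries ran from -1.36 to 1.26 in the list's median. Median, mean and camera's direction differed in sign for monocytes and border macrophages, mural cells and matrix, heat shock genes, inflammatory cytokines and mitochondrially encoded genes.

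The comparison of SN-011 with vehicle asks what the drug did after the occlusion. C3, the central complement component (chromosome 17, 57203970 to 57228136), rose from 3.25 ± 1.58 to 24.1 ± 1.10 CPM. Siglec1, a sialic acid receptor of macrophages (chromosome 2, 131069220 to 131086765), rose from 0.749 ± 0.217 to 6.03 ± 2.99 CPM, and Nr4a3 fell from 58.4 ± 4.58 to 19.4 ± 5.03 CPM (sham, 19.04 ± 0.387). These were the 3 genes called, with log2 fold changes of 2.89 (SE 0.38), 3.004 (SE 0.41) and -1.59 (SE 0.21) and the same adjusted p of 0.0414 by edgeR's quasi-likelihood test. As groups, glial and immune genes had higher medians, but no list held with an estimated correlation (camera, adjusted p = 0.215 for activated microglia) and SN-011 replicate 3 carried much of the difference. Activated microglia genes had a median of 2.09, reactive astrocytes 1.58, complement 1.82 and interferon-stimulated genes 1.19. Without replicate 3 these medians were 0.9997, 0.97, 1.11 and 0.67.

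Adjusted over the list alone, 22 of 23 activated microglia genes, 18 of 26 reactive astrocyte genes, 17 of 36 interferon-stimulated genes, 16 of 24 inflammatory genes and 11 of 16 complement genes were higher. Over all genes tested, only C3 among these was called. Striatal projection neuron genes had a median of -0.26 with no member called by either adjustment (-0.090 without SN-011 replicate 3 and -0.39 without replicate 2). Camera with the preset correlation called 19 lists, 15 higher and 4 lower, and none held with an estimated correlation (camera, adjusted p = 0.215 for activated microglia and 0.251 for interferon-stimulated genes). The 4 lower lists were immediate early genes, striatal projection neurons, neuronal and synaptic genes and mitochondrially encoded genes. Neutrophil and thalamus genes had medians of 0.025 and -0.0096, opposite in sign to camera's direction.

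The count of 3 genes rested on single libraries. It was 0 without any 1 of the 3 vehicle replicates, 1 without SN-011 replicate 1, 513 without replicate 2 and 7 without replicate 3. DESeq2 called 445 genes and edgeR without a filter 601, each including the 3. Without SN-011 replicate 1, C3 and Nr4a3 lost their calls (adjusted p = 0.122 and 0.135). Siglec1 lost its call when these 6 libraries were fitted alone (adjusted p = 0.0822). The groups did not overlap for 16.3% of genes, where chance gives 10%.

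Against sham, the SN-011 arm had 21 genes higher and 0 lower. Some other settings called lower genes too: 27 beside 748 higher without a filter and 27 beside 598 higher by DESeq2. Limma voom with quality weights, added after the data were seen, called 730 lower and 1145 higher. Serpina3n, an acute-phase protease inhibitor of reactive astrocytes, rose from 4.75 ± 0.922 to 238 ± 170.4 CPM, and Tgm1, a transglutaminase of the reactive astrocyte list, from 0.384 ± 0.334 to 12.7 ± 9.80. Among phagocyte genes Gpnmb rose from 1.17 ± 0.366 to 45.98 ± 12.9 CPM, Lgals3 from 1.01 ± 0.154 to 17.5 ± 9.13, Lyz2 (lysozyme) from 7.21 ± 2.38 to 71.8 ± 50.3 and the immune receptor Lilrb4a from 0.222 ± 0.153 to 8.42 ± 7.72. The complement genes C3 and C4b rose by log2 3.63 (SE 0.40) and 2.98 (SE 0.44), and the interferon-induced chemokine Cxcl10 by 5.24 (SE 0.86). By edgeR's quasi-likelihood test the adjusted p was 0.00870 for C3, 0.0157 for Serpina3n and 0.0388 for Cxcl10. Cxcl10 lost its call without SN-011 replicate 1 (adjusted p = 0.0601) or 3 (0.0573), and Gpnmb without replicate 1 (0.0503). The fit of these 6 libraries alone did not call Cxcl10, Lilrb4a, Tgm1, Lyz2 or C4b (adjusted p from 0.135 to 0.153). Without SN-011 replicate 3 the log2 fold changes of Serpina3n, Lilrb4a, Tgm1 and Lyz2 went from 5.65, 5.20, 5.03 and 3.32 to 4.90, 4.12, 4.19 and 2.57, and that of Tgm1 was 5.86 without sham replicate 2. None of these genes was called without any 1 sham replicate. Serpina3n and Lilrb4a have close paralogs with which reads could be shared.

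Adjusted over the list alone, 34 of 36 interferon-stimulated genes, 21 of 23 activated microglia genes and 20 of 26 reactive astrocyte genes were higher than in sham, against 1, 3 and 5 over all genes tested. Camera with the preset correlation called 18 lists, 14 higher and 4 lower, and none held with an estimated correlation (camera, adjusted p = 0.234 for reactive astrocytes and 0.242 for interferon-stimulated genes). Choroid plexus and ependyma genes were among the higher lists, with a median of 0.71 (camera, adjusted p = 0.336 with an estimated correlation) that was 1.41 without sham replicate 1 and 0.31 without sham replicate 3. The count of 21 fell to 0 without any 1 of the 3 sham replicates and was 694 without SN-011 replicate 2, 37 without replicate 3, 625 by DESeq2 and 7 in these 6 libraries alone. The groups did not overlap for 25.6% of genes, where chance gives 10%.

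**Figure D2:**
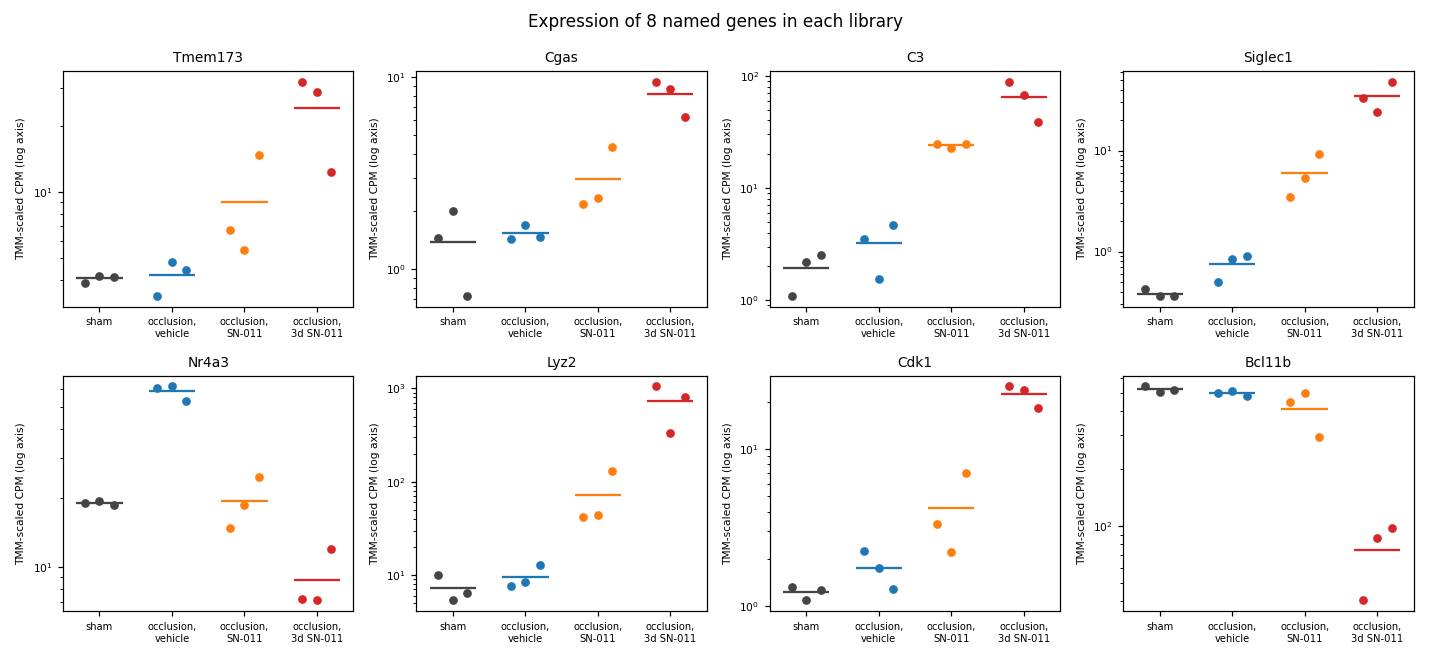
Each panel plots TMM-scaled CPM on a log axis (y axis) for 1 gene in each of the 12 libraries, by group (x axis). Points are libraries and bars group means. Tmem173, Cgas, C3, Siglec1, Lyz2 and Cdk1 had their highest mean in the 3d arm, Nr4a3 had its highest mean in vehicle, and Bcl11b had its lowest in the 3d arm.

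The comparison of the 3d SN-011 arm with vehicle asks how the second arm under the drug stood against occlusion without it. No vehicle or sham library carries the prefix 3d, so an effect of the drug cannot be told apart from whatever 3d stands for. The same holds for the 3d arm against sham. All 28 striatal projection neuron genes fell, with a median of -2.69 on the log2 scale, and 24 of 25 neuronal and synaptic genes fell. Bcl11b, a transcription factor of these neurons, fell from 497 ± 17.6 to 74.96 ± 30.4 CPM, and Cnr1, the cannabinoid receptor, from 503 ± 49.5 to 37.5 ± 19.6. Neurofilament light chain Nefl fell by 2.47 (SE 0.23) and the synaptic gene Cplx2 by 2.34 (SE 0.25), both on the log2 scale. All 23 activated microglia genes rose, with a median of 4.66: Lyz2 rose from 9.63 ± 2.84 to 731 ± 365 CPM and Lgals3 from 1.86 ± 0.955 to 126 ± 87.96 (log2 fold change 6.08, or 5.40 without 3d replicate 3).

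Other immune and glial groups rose with them. All 36 interferon-stimulated genes rose, with a median of 2.86, among them Ifitm3 by 3.12 (SE 0.36) and Stat2 by 1.33 (SE 0.17). Of 26 reactive astrocyte genes 23 rose, and S1pr3, a sphingosine phosphate receptor, went from 9.43 ± 2.59 to 104 ± 29.1 CPM. All 28 cell cycle genes rose: Cdk1 went from 1.76 ± 0.481 to 22.3 ± 3.52 CPM and Pcna from 33.8 ± 2.22 to 79.9 ± 5.55. All 23 genes of pyroptosis, necroptosis and apoptosis rose, including the TNF receptor Tnfrsf1a by 3.57 (SE 0.35) and Bid by 2.26 (SE 0.23). Of 24 inflammatory genes 21 rose, including Tgfb1 by 3.87 (SE 0.35) and Lif by 4.04 (SE 0.48). Homeostatic microglia (15 of 16), antigen presentation (19 of 20), complement (13 of 16), monocytes and border macrophages (13 of 15) and lymphocytes (8 of 10) also had mostly higher members. For the 16 genes named by list here and above the adjusted p of edgeR's quasi-likelihood test lay between 1.22e-05 and 4.03e-05, Srgn of the reactive astrocyte list (2.89, SE 0.26) included.

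Lists of other cell types and programmes went both ways. All 12 oligodendrocyte precursor genes rose with a median of 1.05, 9 of 17 oligodendrocyte and myelin genes rose with a median of 0.50, and 10 of 15 resting astrocyte genes, 13 of 19 endothelial genes and 15 of 20 mural cell and matrix genes rose, the last with a median of 2.31 that 3d replicate 2 hardly shared (list medians over sham 2.28, 0.53 and 2.66 in replicates 1 to 3). Among immediate early genes 11 of 19 fell and 3 rose, with a median of -2.44. Of heat shock, hypoxia and oxidative stress genes 8 of 21 rose and 4 fell, of subventricular neuroblast genes 6 of 12 rose and 2 fell, and of 5 neutrophil genes 2 rose. Genes of neighbouring tissue went both ways. Of choroid plexus and ependyma genes 5 rose and 9 fell (median -1.99), a fall that 3d replicate 2 shared least. Their list medians over sham were -1.56, 0.35 and -1.38 in 3d replicates 1 to 3. Of cortical projection neuron genes 1 rose and 2 fell, and of 9 thalamus genes 3 rose and 1 fell. Of 5 red blood cell genes 2 fell, and of 13 mitochondrially encoded genes 6 fell. Adjusted over the list alone, the higher members were 23 of inflammatory, 25 of reactive astrocyte, 16 of homeostatic microglia, 14 of monocyte and border macrophage, 14 of complement, 9 of stress and 6 of choroid plexus genes. By the same adjustment 1 complement gene, 1 endothelial gene and 10 choroid plexus genes were lower. In every other list named here both adjustments gave the same counts.

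The genes with the largest rises were near or below detection in vehicle. Sucnr1, the succinate receptor, had no count in vehicle and was at least 75.6-fold higher, against a floor of 3 counts over the group. On the same floor Bcl2a1d was at least 46.7-fold, Hmga2 at least 46.6-fold and the cytokine Tnf at least 38.04-fold higher. The bound of Sucnr1, at 4.83 ± 5.36 CPM in the 3d arm, was 27.9-fold without 3d replicate 2. Without vehicle replicate 1, which leaves fewer reads under the floor, the bounds of the 4 genes were 49.8, 30.8, 30.7 and 25.1. Cd5l, a macrophage-secreted protein, rose from 0.127 ± 0.129 to 48.5 ± 18.1 CPM, by 8.49 on the log2 scale and by 9.41 without vehicle replicate 3. The largest falls were those of the orphan receptor Gpr139 (19.7 ± 3.78 to 0.414 ± 0.589 CPM), Gpx6 (3.32 ± 0.266 to 0.116 ± 0.124), Cdh3 (2.98 ± 1.59 to 0.136 ± 0.126), the antisense transcript AC132106.1 (3.20 ± 1.49 to 0.153 ± 0.148) and Impg1 (7.52 ± 1.17 to 0.392 ± 0.355). Without 3d replicate 2 the log2 fold changes of these 5 moved from -5.51, -4.72, -4.37, -4.31 and -4.23 to -7.84, -5.80, -5.11, -5.22 and -4.94. The strand setting of the counting is not given, so reads of AC132106.1 and of a gene on the other strand cannot be told apart, and Bcl2a1d has near-identical copies. Cdh3 was not called by limma voom with quality weights, added after the data were seen (adjusted p = 0.116).

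In all, edgeR's quasi-likelihood test called 10584 genes between the 3d arm and vehicle, 5355 higher and 5229 lower. With offsets for GC content and length, added after the data were seen, the balance turned to 4949 higher and 5811 lower. The groups did not overlap for 59.4% of genes, where chance gives 10%. At an absolute log2 fold change of at least 1 the count was 6154. Camera with the preset correlation called 21 of 28 lists, 17 higher and 4 lower, and none held with an estimated correlation (camera, adjusted p = 0.315 for activated microglia, striatal projection neurons, interferon-stimulated genes and cell cycle alike). The 3d libraries had TMM factors between 1.04 and 1.09, against 0.958 to 0.984 in vehicle. The median of cortical genes was 0.063 and their mean -0.10.

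The comparison of the 3d arm with the other SN-011 arm asks how the 2 arms differ under the same treatment label. All 28 striatal projection neuron genes were lower in the 3d arm, with a median of -2.46, and 23 of 25 neuronal and synaptic genes were lower too. Bcl11b fell by 2.46 (SE 0.28), Cnr1 by 3.14 (SE 0.40), Nefl by 1.93 (SE 0.22) and Cplx2 by 2.09 (SE 0.24) on the log2 scale. All 28 cell cycle genes and all 23 cell death genes were higher, including Cdk1 by 2.40 (SE 0.35), Pcna by 0.96 (SE 0.11), Bak1 by 1.40 (SE 0.20) and Bid by 1.52 (SE 0.22). Of 23 activated microglia genes 21 were higher, with Lyz2 at 3.35 (SE 0.50) and the fatty acid binding protein Fabp5 at 1.36 (SE 0.20). Without SN-011 replicate 3 the values of Cdk1 and Lyz2 were 2.99 and 4.09.

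Of 36 interferon-stimulated genes 30 were higher in the 3d arm, Ifitm3 by 1.85 (SE 0.34) and Stat2 by 0.91 (SE 0.17). Of 26 reactive astrocyte genes 22 were higher, Srgn by 2.04 (SE 0.25) and the cytokine Clcf1 by 2.23 (SE 0.32), and of 24 inflammatory genes 18 were higher, Tgfb1 by 2.28 (SE 0.32) and Nfkbia by 1.51 (SE 0.23). Adjusted over the list alone, 31 interferon-stimulated, 19 inflammatory and 23 activated microglia genes were higher, and the counts for reactive astrocytes, cell cycle, cell death and both neuronal lists stayed as given. Among the largest rises, Serpina3m had 1 count in the other arm and was 102-fold higher (95% counting interval 17.9 to 4064), and Apoc4 had 3 counts and was 38.8-fold higher (12.99 to 191). These intervals and floors cover counting error only, and DESeq2 did not call Apoc4 (adjusted p = 0.136). Xlr4a, the macrophage chitinase-like gene Chil3 and Ms4a4a rose by 4.77, 4.69 and 4.68 with SEs of 1.18, 1.20 and 0.95. Single libraries carried these rises. Without 3d replicate 3 Serpina3m was 30.4-fold and Apoc4 17.2-fold higher, and Chil3 and Ms4a4a rose by 2.47 and 2.99, while Xlr4a rose by 3.10 without 3d replicate 2. SN-011 replicate 3 held all counts of Serpina3m and Apoc4 in its arm: without it they were at least 22.96-fold and 26.1-fold higher, and Xlr4a and Chil3 rose by 5.96 and 5.71. Serpina3m, Xlr4a, Chil3 and Ms4a4a belong to families with close copies, so their counts are uncertain. Gpr139, Gpx6, AC132106.1, Cdh3 and Trim71 fell most, with log2 fold changes of -4.77, -4.55, -3.97, -3.96 and -3.73. Without 3d replicate 2 the first 4 were at -7.10, -5.63, -4.87 and -4.70. Cdh3 was not called by limma voom with quality weights, added after the data were seen (adjusted p = 0.108).

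EdgeR's quasi-likelihood test called 8607 genes between the SN-011 arms, 4367 higher and 4240 lower in the 3d arm (2743 higher and 3088 lower in these 6 libraries alone, 3217 higher and 3609 lower without SN-011 replicate 1, 2981 higher and 3329 lower without SN-011 replicate 2, 3707 higher and 3718 lower without 3d replicate 1 and 4158 higher and 4271 lower without 3d replicate 2), and 4437 at an absolute log2 fold change of at least 1. The groups did not overlap for 50.3% of genes, where chance gives 10%. Camera with the preset correlation called 19 lists, 16 higher and 3 lower, and none held with an estimated correlation (camera, adjusted p = 0.341 for striatal projection neurons and for the cell cycle).

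Against sham, the 3d arm showed the same groups: all 36 interferon-stimulated, 23 activated microglia, 28 cell cycle and 23 cell death genes rose, and all 28 striatal projection neuron genes fell, with a median of -2.68. These counts were the same adjusted over the list alone. Cst7, a cathepsin inhibitor of activated microglia, had 3 counts in sham and was 1414-fold higher (95% counting interval 484 to 6858), and Cd5l had 2 counts and was 1193-fold higher (329.8 to 9852). The antiviral gene Oas3 and Sucnr1 had no count in sham and were at least 97.5-fold and 79.8-fold higher. Without sham replicate 2, which held these counts of Cst7 and Cd5l, the 2 genes were at least 928-fold and 534-fold higher, and without sham replicate 3 Cd5l was 794-fold higher. The bound of Sucnr1 was 29.5-fold without 3d replicate 2, and those of Oas3 and Sucnr1 were 64.9-fold and 53.1-fold without sham replicate 3. Gpnmb rose from 1.17 ± 0.366 to 625 ± 568 CPM, Clcf1 from 1.62 ± 0.195 to 28.4 ± 3.46, the chemokine Ccl12 from 0.202 ± 0.0699 to 14.5 ± 6.54 and Bax from 18.96 ± 0.941 to 41.9 ± 2.92. Gpx6, Gpr139, AC132106.1, Impg1 and the noncoding transcript AU023762 fell most, with log2 fold changes of -5.55, -5.53, -4.55, -3.999 and -3.92. Without 3d replicate 2 they were at -6.63, -7.86, -5.45, -4.71 and -5.24, and Gpnmb moved from 9.05 to 8.10 without 3d replicate 3. The count was 10684 genes by edgeR's quasi-likelihood test, 5516 higher and 5168 lower (5032 higher and 5929 lower with offsets for GC content and length), and 6269 at an absolute log2 fold change of at least 1. The groups did not overlap for 63.3% of genes, where chance gives 10%. Camera with the preset correlation called 18 lists, 14 higher and 4 lower, and none held with an estimated correlation (camera, adjusted p = 0.340 for activated microglia). Choroid plexus and ependyma genes had a median of -1.47, opposite to camera's direction. By library their medians were -1.56, 0.35 and -1.38 in 3d replicates 1 to 3 and 1.26, 0.28 and -1.36 in the sham replicates, so the groups overlapped.

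The drug's target pathway was followed in each comparison. STING itself, listed as Tmem173 (chromosome 18, 35733679 to 35740554), stood at 4.06 ± 0.157 CPM in sham, 4.21 ± 0.748 in vehicle, 8.998 ± 5.06 in SN-011 and 24.3 ± 10.5 in the 3d arm. It rose in the 3d arm over vehicle by 2.53 (SE 0.40; edgeR quasi-likelihood test, adjusted p = 1.85e-04) and over the other SN-011 arm by 1.43 (SE 0.38; adjusted p = 0.00827), a call lost when the 6 libraries of the SN-011 arms were fitted alone (adjusted p = 0.0529). SN-011 against vehicle missed the threshold (1.10, SE 0.40, adjusted p = 0.314). SN-011 against sham missed it too, but was called by edgeR's quasi-likelihood test without a filter (1.15, adjusted p = 0.0307). Cgas, the DNA sensor that activates STING (chromosome 9, 78430526 to 78443237), stood at 1.54 ± 0.136 CPM in vehicle, 2.95 ± 1.19 in SN-011 and 8.14 ± 1.68 in the 3d arm, where it rose over vehicle by 2.40 (SE 0.36; edgeR quasi-likelihood test, adjusted p = 1.34e-04) and over the other SN-011 arm by 1.46 (SE 0.34; adjusted p = 0.00421). Irf3, the transcription factor downstream (chromosome 7, 44997648 to 45002848), rose in the 3d arm over vehicle by 0.79 (SE 0.18; edgeR quasi-likelihood test, adjusted p = 0.00214), a call that offsets for GC content and length ended (log2 fold change 0.37, adjusted p = 0.0526). The kinase Tbk1 (chromosome 10, 121546455 to 121586787) lay between 44.4 ± 2.09 and 51.2 ± 2.88 CPM over the 4 group means and was called in none of the 6 comparisons, though it was lower than in sham without 3d replicate 3 (-0.38; edgeR quasi-likelihood test, adjusted p = 0.00848). Ifnb1, the interferon induced by the pathway (chromosome 4, 88522025 to 88522774), had 0 counts in all 12 libraries. Of the 14 pathway genes tested, 11 rose in the 3d arm over vehicle, 10 over the other SN-011 arm and 1 in the SN-011 arm over sham. The numbers adjusted over the list alone were 13, 12 and 6. Camera's call of this list in each of those comparisons was lost with an estimated correlation (adjusted p = 0.315, 0.341 and 0.242). In the 3d arm over vehicle the list's median was 1.90, below homeostatic microglia (2.67) and above oligodendrocytes and myelin (0.50). That comparison called 57.1% of all genes tested, so the rise was not shown to be particular to the pathway. RNA levels also do not measure how far SN-011 inhibited STING.

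Whether SN-011 moved genes back from their change under the occlusion was asked through the covariance of fold changes over the 18537 genes tested. Since 0 genes were called between vehicle and sham, no share of called genes with the opposite sign could be given. Between vehicle minus sham and SN-011 minus vehicle the covariance was -0.0251, against -0.0344 in 100 simulations of unchanged groups that share the vehicle libraries. For the 3d arm it was -0.0155 against -0.0343. The correlations across genes, which are not independent replicates, were -0.184 and -0.0390 against simulated values of -0.510 and -0.515. Signs were opposite for 57.5% and 50.9% of genes, against 66.8% and 67.02%. The simulated arms had no changes of their own, while the real log2 fold changes over vehicle had SDs of 0.54 and 1.38 across genes. Changes unrelated to the occlusion also weaken the correlation and the share of opposite signs, so these 2 measures cannot decide on movement back. Both covariances were less negative than sharing the vehicle libraries gave in the simulations, where movement back towards sham would be more negative. Set against the spread of the vehicle libraries, a value chosen after the covariances were seen, the excess of 0.0165 and 0.0261 turned to -0.0158 and -0.0293 without vehicle replicate 3, so its direction rests on that library.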

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

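The tests of vehicle power, of exchanged libraries or labels, of choroid plexus, of a batch and of neuron share were chosen after the results they measure were seen. For tissue mixture, GC content and length, and other splits, the bounds were written before the values they are held to were computed. The offsets for GC content and length and the test of tissue mixture were themselves added after the data were seen.

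The change from the vehicle libraries differed between the 2 SN-011 arms for 8607 genes (edgeR quasi-likelihood test of the 3d arm against the other arm), which is what singled this result out. Of the 10 splits of these 6 libraries, 1 gave as many calls, the real one, and the highest of the others gave 2. The 10 splits of 3 against 3 are too few for a share under 0.05. For the other comparisons the real count and the highest of the other 9 splits were 10584 and 0 for the 3d arm against vehicle, 10684 and 0 for the 3d arm against sham, 21 and 0 for SN-011 against sham, and 3 and 0 for SN-011 against vehicle. In each of these 1 of the 10 splits reached the real count. For vehicle against sham all 10 splits reached it, since the real count was 0 and the highest other was 0.

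A set of 3 explanations was weighed for the 10584 genes called in the 3d arm. After offsets for GC content and transcript length 9147 of them kept their sign and call, which argues against such a bias as the whole cause. The slope of SN-011 minus sham on 3d minus vehicle, 2 differences with no library in common, was 0.257 over all genes tested (0.152 to 0.337 with each library left out), which argues against a batch effect confined to the 3d libraries as the whole cause. A lower share of neurons that raises all other cell types alike was argued against as the whole cause. The median of activated microglia exceeded that of oligodendrocytes and myelin by 4.16 on the log2 scale (3.92 to 4.46). That microglia list marks activation as well as cell number, so a lower share of neurons as part of the cause stays open. Also open and untested is a difference in time after occlusion, dosing or lesion size between the 3d libraries and the others, which the prefix 3d may stand for.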

How the results depend on the processing

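The total counts for the 3d arm were stable, though not their balance of higher and lower genes, and those of the other comparisons were not. For vehicle against sham (0 genes), SN-011 against vehicle (3) and SN-011 against sham (21), the count was 5, 601 and 775 without a filter, 3, 445 and 625 by DESeq2, and 16, 5 and 7 in the 6 libraries compared. With settings added after the data were seen it was 1, 17 and 39 without the 3d arm, and 32, 1179 and 1875 by limma voom with quality weights. With offsets for GC content and length, vehicle against sham had 1. The cause was not tested. Leaving out 1 replicate gave 0 to 513 genes for SN-011 against vehicle and 0 to 694 for SN-011 against sham, and 0 throughout for vehicle against sham. The highest of these were without SN-011 replicate 2, and the 0 counts without any 1 vehicle or sham replicate. Of the 3d arm's counts, an absolute log2 fold change of at least 1 left 6154 against vehicle, 4437 against the other SN-011 arm and 6269 against sham, by its own construction. Leaving out 1 replicate gave 9354 to 11047, 6310 to 9307 and 9242 to 11095, and the other settings stayed within 1.5 times.

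The numbers of lists called by camera (9, 19, 21, 19, 18 and 18) became 0 in each of the 6 comparisons with an estimated correlation. With the correlation estimated in 6 libraries, an alternative added later, they became 0 in 5 and 1 in the 3d arm against sham. Leaving out 1 replicate gave 4 to 8 lists for vehicle against sham, with the lowest without vehicle replicate 3. Of the single list calls, 584 held with 1 replicate left out and 40 did not, and no list changed direction under the alternatives run.

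Replicate numbers did not pair the libraries: 2 of 18 same-numbered pairs had a correlation of deviations over 0.1, as had 5 of 36 others, and 4 of 12 libraries correlated best with their own number. With the replicate number as a block, SN-011 against vehicle had 19 genes, vehicle against sham 0, SN-011 against sham 28, and the 3d arm 10261 against vehicle, 8142 against the other arm and 10324 against sham. In the blocked fit the 2 SN-011 arms had 4045 higher and 4097 lower, a turned balance. The blocked fit called 8, 19, 21, 19, 18 and 19 lists. Among the named genes it did not call Cxcl10 in SN-011 against sham (adjusted p = 0.0633) and changed no other call.

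Of the named genes, 632 results with 1 replicate left out kept direction and call, 44 lost the call, 1 gained it and 7 changed sign. Fitting the 6 libraries compared ended 8 calls of named genes, voom 2, GC content and length offsets 2, DESeq2 1 and the replicate block 1. The fit with no filter added 1, that of Tmem173 in SN-011 against sham. The sign changes were of uncalled genes. Tbk1 in the 3d arm against vehicle ran from -0.26 to 0.084 with 1 replicate left out, at 0.033 without vehicle replicate 2 and 0.084 and 0.079 without 3d replicates 1 and 2. Against the other SN-011 arm it ran from -0.18 to 0.16, at -0.18 without 3d replicate 3 and -0.065 by voom. For vehicle against sham Cgas ran from -0.17 to 0.49, Tmem173 from -0.056 to 0.19 and Irf3 from -0.038 to 0.27. Cgas was at -0.17 without sham replicate 3, Tmem173 at -0.056 without vehicle replicate 2 and -0.092 by voom, and Irf3 at -0.038 without vehicle replicate 3. The cause was not tested. The excess covariance over the spread of the vehicle libraries, a form chosen after the values were seen because leaving out a library changes the value that sharing gives, ran from -0.0158 to 0.0360 for SN-011 and from -0.0293 to 0.0610 for the 3d arm, negative without vehicle replicate 3. Ifnb1 had 0 counts in all 12 libraries, for which lack of expression and too few reads were not told apart.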

Other observations

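The gene groups and the tests in this part were chosen after the data were seen, and only the bound for tissue mixture was written before its value was computed. Of 8 gene groups defined by their names, cytosolic ribosomal proteins rose most uniformly: 74 of 81 rose and 1 fell in the 3d arm over vehicle, with a median of 1.03 on the log2 scale (camera, adjusted p = 1.93e-17 with the preset and 0.317 with an estimated correlation). Ribosomal proteins have many processed pseudogenes with which reads could be shared. Of 41 collagens 25 rose and 6 fell, but Col1a1, at 7.78 ± 0.412 CPM in vehicle, stood at 160.4, 10.3 and 362 in the 3d replicates, so that replicate 2 lacked most of its rise. Of 12 GABA-A receptor subunits 11 fell, with a median of -1.90, and of 20 voltage-gated potassium channels 13 fell and 1 rose, among them Kcna4 from 87.3 ± 12.5 to 10.5 ± 5.37 CPM. Of 19 phosphodiesterases 10 fell and 3 rose, including the striatal Pde10a from 2476 ± 258 to 240.2 ± 149 CPM. Camera's adjusted p for these 4 groups with an estimated correlation was 0.420 for collagens and 0.317 for each of the others. Of 36 nuclear-encoded complex I subunits 4 rose and 8 fell, of 38 proteasome subunits 8 rose and 5 fell, and of 18 vacuolar ATPase subunits 4 rose and 10 fell, none called by camera.

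The size of the SN-011 arm's change relative to that of the 3d arm was computed for 28 lists, 9 of which are given, and no difference between lists was tested. The medians here are of differences in mean log2 CPM, which differ from the fitted log2 fold changes given elsewhere. As a percentage of the 3d arm's median over vehicle, the SN-011 arm's median over sham was 55.9% for interferon-stimulated genes (39.2% to 75.8% with each library left out), 51.5% for reactive astrocytes (41.6% to 62.7%), 38.8% for activated microglia and phagocytosis (23.4% to 46.1%), 17.99% for neuronal and synaptic genes (8.21% to 25.9%), 9.34% for striatal projection neurons (1.27% to 14.5%), 4.71% for oligodendrocytes and myelin (-11.1% to 34.2%) and 90.1% for mitochondrially encoded genes (65.5% to 113%). The value was -21.1% for endothelium and blood-brain barrier (-32.8% to -14.3%) and -51.3% for choroid plexus and ependyma (-82.1% to -16.01%), where the 2 medians had opposite signs. Rises and falls cannot be ranked from these ratios of log2 values: on the CPM scale SN-011 replicate 3 stood further along the genes that fell (43.6% to 53.9% of the way from sham to the 3d libraries) than along those that rose (32.98% to 41.4%). The percentages also rest on 2 baselines, so a list that differs between vehicle and sham is shifted. Against vehicle, fitted medians of the SN-011 and 3d arms were 1.19 and 2.86 for interferon-stimulated genes and 1.58 and 3.57 for reactive astrocytes. They were 2.09 and 4.66 for activated microglia and 0.048 and 0.89, of like sign, for endothelium. Choroid plexus kept opposite signs (0.099 and -1.99). The order of the lists is therefore not settled.

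An injury axis was set up as the median oriented log2 change from sham over the 10684 genes called in the 3d arm against sham. Vehicle replicates 1 and 2 scored 0.0135 and 0, near the sham libraries (-0.0140 to 0.00809), and vehicle replicate 3 scored 0.0866, above them and above SN-011 replicate 2 (0.0754). Over the 8607 genes called between the SN-011 arms, signed by their direction in the 3d arm, the oriented change of vehicle from sham was 0.0650 of that of SN-011 from sham (-0.0424 to 0.131 with each sham or vehicle library left out and 0.126 without SN-011 replicate 3). For these genes and this direction, that argues against a response as large as the SN-011 arm's that the test merely lacked power to call. A vehicle response in other genes or in the other direction was not measured by this ratio. An exchange of vehicle replicate 3 and SN-011 replicate 2 was not decided by this axis (lowest SN-011 minus highest vehicle score -0.0113, sham range 0.0221). Gpnmb (5.21 against 52.9 CPM), Spp1 (5.98 against 98.4), C3 (4.70 against 22.9) and Nr4a3 (53.2 against 18.7) differed between the 2 libraries. These genes were called or picked with the present labels, so their values cannot count against an exchange. On genes chosen without both libraries SN-011 replicate 2 led by 0.109 of the way between the groups, beyond the sham range of 0.0483 first set as the bound. Libraries of 1 group lay 0.563 apart, a bound added after the values were seen, so the exchange stays open. By this bound an exchange of any vehicle library with SN-011 replicate 1 or 2 stays open too. For vehicle replicate 1 and SN-011 replicate 1 the lead was 0.693 against 0.931 within a group. For replicates 2 of both groups it was 0.256 against 0.574. Only the pairs with SN-011 replicate 3 lay apart, with a smallest lead of 1.52 against 0.297. No value separates an exchange of the whole groups' labels, or tissue outside the lesion, from a weak or early response in the vehicle animals.

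SN-011 replicate 3 stood apart in its arm, with a score of 0.463 against 0.215 and 0.0754. On the CPM scale its position between sham and a library of the 3d arm was 32.98% to 41.4% by the 3545 genes that rose at least 2-fold and 43.6% to 53.9% by the 2724 that fell. The 2 shares differed by 1.19 to 1.32 times, under the bound of 1.5, so a mixture of injured and intact tissue may account for it. A uniformly milder response was not told apart from a mixture. More choroid plexus in the dissection is argued against: of 3 libraries with a like choroid plexus median, the highest score was 0.463 of that of replicate 3, just under a bound of 0.5 that replaced an earlier form of this test, and the others, sham replicate 1 and vehicle replicate 2, scored 0.00742 and 0.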
